A study of Macaca fuscata with 12 samples.

How the data were processed

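Expression was measured on 12 Affymetrix rhesus macaque arrays, each hybridised with RNA from the left hemisphere of 1 of 8 Japanese macaques (Macaca fuscata). Per the labels, 6 arrays held tissue from around the lateral sulcus that includes the secondary somatosensory cortex (SII), and 6 held tissue from around the intraparietal sulcus (IPS). In each region 3 arrays came from animals trained in tool use and 3 from control animals. Of the 8 animals, 4 gave tissue from both regions. The labels' protocols state that total RNA was purified with the RNeasy Lipid Tissue Mini Kit, checked on a Bioanalyzer, and turned into biotinylated cRNA with the 3' IVT kit. Groups, replicate numbers, sex, age and animal were taken from the labels.

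The deposited values are log2 expression values per probe set, which the authors centred so that the median of each probe set over the 12 arrays is 0 (largest deviation 2.5e-07). The log base is not given in the sources used here and was inferred from the range of the values. MAS5 is the tool named per the submitters' processing notes, without a version. The scaling between arrays is not given in the sources used here, and the values were used as deposited because the array medians lay within 0.2 of each other. Centring removes the level of each probe set, so a value gives a probe set's position relative to its own median and no level or detection call. Of 52865 probe sets, 99 controls were left out and 52766 were tested. The array's gene table gave 1 symbol to 24956 of these, several to 361 and none to 27449, and 1691 of the single symbols were locus names. Genome coordinates were not used here.

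A rough signal level was recovered from the spacing of the single-precision numbers, which widens with the signal before centring. In this way 4479 probe sets had a high signal (at least 256 in at least 11 of 12 arrays), 20852 a middle signal (at least 16) and 17517 a low signal. A further 9918 probe sets (18.8%) carried 1 lowest value in at least 2 arrays, here called the floor. It was recognised because many probe sets shared the same difference between a pair of arrays (at least 1065 in each pair, against at most 14 for the next most common difference). The floor had been set before the arrays were scaled, so its position differed between arrays by up to 1.67 log2 units. A value at the floor is only an upper limit, values at the floor have no order, and a floor in a single array cannot be seen. The floor was found after the first results had been seen, and the signal levels, which had placed 917 floor probe sets among the high ones and 5532 among the middle ones, were then corrected. The median SD within groups was 0.23 for high, 0.37 for middle, 0.78 for low and 1.03 for floor probe sets. The number of arrays limits the precision, with a median standard error of 0.44 log2 units for a training change within 1 region.

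Each probe set was fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 4 group means, the correlation between arrays of the same animal estimated over all probe sets (0.0474), and empirical Bayes moderation. The residual degrees of freedom were 8 and the prior ones 2.22. Benjamini-Hochberg adjustment was applied over all probe sets of a comparison, with a false discovery rate of 0.05. The comparisons were trained against control in SII, the same in IPS, the difference between these changes, their average, and IPS against SII averaged over training. All tests were 2-sided. A single comparison of 3 arrays with 3 cannot give an exact permutation p below 0.10, so the fitted model carries the tests.

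The comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. For SII and IPS the rule named up to 12 higher and 12 lower genes past 5% by size of change. Where fewer passed, probe sets with non-overlapping groups and an absolute log2 change of at least 0.58 were added by ascending p, as values that did not pass. For the difference and the average it named up to 6 per direction. Genes of the lists were named by the 2 smallest p, with every neurotrophin gene added. Centring forced departures from the chosen design: no filter on the mean level and no trend in the moderation could be used, and the values of all probe sets of a gene were averaged for gene and list tests (14132 genes), because the probe set with the highest level could not be picked.

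The 29 lists (568 measured members, lists under 5 members not tested) were tested with limma's cameraPR at a preset correlation between genes of 0.01. An estimated correlation and fry were run beside it. Members were also adjusted over the list alone. Alternatives covered quantile normalization, median centring, array weights, sex, age, the animal correlation, a replicate block, each array left out, male animals only, each region fitted alone, a plain 2-sample test, and the 4 animals with both regions. Chosen after seeing the data were fits with high or middle signals only, with the actin 3' minus 5' difference as an RNA quality term, without 3 arrays with raised hybridisation controls, without floor probe sets, with 1 common floor for all arrays, and list tests with the correlation estimated in each of the alternative fits. Other splits of the samples and 10000 shuffles of gene names were also run. The procedure was tested on 20 simulated tables with 200 changed probe sets each. A log2 change of 2 in SII was recovered in 83.7% of high, 54.0% of middle, 15.7% of low and 6.44% of floor probe sets. In the simulations 6.42% of calls were unchanged probe sets. The simulated values had the spread of each probe set but no floor, and no structure between arrays beyond the animal. The share for floor probe sets therefore reflects their spread alone. A shift of 0.5 in 1 list, the mitochondrial respiratory chain, was recovered in 20 of 20 tables. The genes were simulated as independent, while the estimated correlation of this list in the data was 0.186. The recovery therefore does not carry over to lists of correlated genes. Summaries and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.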

Results

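Gene expression was compared between macaques trained in tool use and control animals in 2 parts of the left cerebral cortex. The groups were SII control, SII trained, IPS control and IPS trained, with 3 arrays each. The array SII control 1 and the array SII trained 2 came from female animals, and the other 10 came from males. Values are log2 units relative to the median of each probe set over the 12 arrays. Nothing in the labels gives a hybridisation date. The arrays of the regions carry different names in the labels, so region and hybridisation batch may coincide.

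The arrays differed in several ways, most of which the groups do not explain. The 27 probe sets of the bacterial and phage hybridisation controls lay at 0.45 in SII control 1, 0.54 in SII trained 2 and 0.46 in IPS trained 3, against -0.13 to 0.08 in the other arrays. The first principal component, with 17.3% of the variance, placed the arrays of the female animals at 130 and 161 and all others between -56.6 and 20.4. A probe set without a gene symbol, chosen after its values were seen, lay at 10.92 and 10.98 in the female animals and between -0.74 and 0.20 in the males. The alpha globin gene HBA lay at 4.04 in SII trained 2 and 2.33 in IPS trained 1, against at most 0.96 in the other arrays. Between 3.63% (SII control 2) and 9.77% (SII trained 2) of the probe sets of an array lay at the floor. The actin 3' minus 5' difference, a reading of RNA quality, ran from -1.87 (SII control 2) to 1.37 (IPS trained 3). The same difference for GAPDH was -0.51 to -0.27 in the SII controls and -0.23 to 0.77 in the SII trained arrays. RNA quality as read by GAPDH thus went with training in SII, while the IPS groups overlapped.

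**Figure D1:**
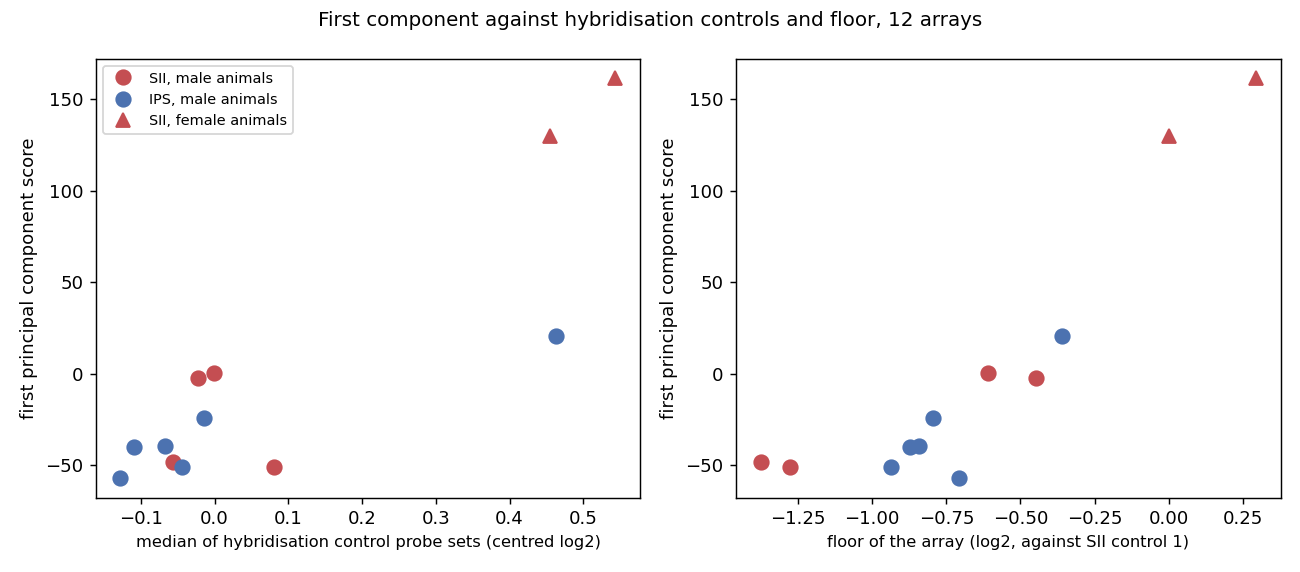
Score of each of the 12 arrays on the first principal component against the median of the hybridisation control probe sets (left, centred log2) and against the floor of the array (right, log2 relative to SII control 1). The arrays of female animals (triangles) lie at 130 and 161, above all arrays of males (circles, at most 20.4), with hybridisation controls of 0.45 and 0.54 and floors of 0 and 0.29.

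Around the lateral sulcus, NKG7, which encodes a granule protein of natural killer and cytotoxic T cells, was higher in trained than in control animals by 2.71 ± 0.33 log2 units (SE, n = 3 per group). Its group means were -1.91 ± 0.34 in controls and 0.81 ± 0.47 in trained animals (SD), and all 3 trained arrays lay above all 3 controls. RET, the signalling receptor for the GDNF family of neurotrophic factors, was lower in trained animals, with a change of -1.77 ± 0.37 and group means of 1.66 ± 0.48 and -0.10 ± 0.67. FOXP2, a transcription factor listed here among markers of the hippocampus and amygdala, had a change of 0.86 ± 0.21 over 5 probe sets. Of these, 1 lay at the floor in 4 arrays (SII control 2, SII control 3, SII trained 2 and IPS trained 3), so the size rests partly on the floor. With p adjusted over the list alone, these 3 genes passed 5% in limma (NKG7 7.27e-05, RET 0.0059, FOXP2 0.0184), and 0 of 14132 genes passed over all genes, where NKG7 had an adjusted p of 0.0934 and RET of 0.926. As many as 3 genes past 5% over a list alone came up in 9.07% of 10000 shuffles of gene names. FOXP2 lost its call in 12 of 26 alternatives (adjusted p over the list alone from 0.0102 to 0.806), and its change ran from 0.63 to 1.13.

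Of the RET probe sets, 1 lay at the floor in 5 arrays (0 SII control, 1 SII trained, 1 IPS control, 3 IPS trained) and changed by -2.21 ± 0.38 in SII. The other, with a low signal and no floor found, changed by -1.32 ± 0.57. Without floor probe sets RET kept its direction in SII but lost its call (-1.32 ± 0.55, adjusted p over the list alone 0.288, range over alternatives 0.00225 to 0.288). The other neurotrophin genes had changes of 0.38 ± 0.41 for BDNF, 0.02 ± 0.40 for NTF3, 0.25 ± 0.39 for NTF4, 0.08 ± 0.20 for NTRK3, -0.30 ± 0.40 for NGFR, 0.48 ± 0.34 for GFRA1 and -0.17 ± 0.43 for GFRA2. GDNF itself had a change of 0.58 ± 0.25, but 2 of 3 control arrays and 1 of 3 trained arrays lay at the floor, and with 1 common floor the change was 0.06 ± 0.20.

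The rule named 12 higher and 12 lower genes in SII, none of which passed over all probe sets (adjusted p from 0.150 for NKG7 to 0.911 for DCTN5 and FHAD1). Among the higher ones with no floor found were HOXB8, a homeobox gene of axial patterning, at 2.49 ± 0.39 with the same sign in 4 of 4 other probe sets, SP110 at 2.63 ± 0.44 (1 of 5 others), ZNF226 at 2.30 ± 0.39 (2 of 3), POU5F1 at 1.46 ± 0.29, CDH23 at 2.73 ± 0.57 and ATP1A4 at 2.90 ± 0.61. Among the lower ones were ASB12 at -1.84 ± 0.36, PPP1R10 at -2.56 ± 0.51, TSHR, the thyrotropin receptor, at -2.02 ± 0.42, RHBDD1 at -1.44 ± 0.34 (2 of 2), HYAL1 at -1.67 ± 0.40, DCTN5 at -0.91 ± 0.23 and C20H16orf78 at -2.29 ± 0.51. The remaining 10, whose sizes rest partly on the floor, were ACOD1, KLK3, ICE1, HKDC1 and GARIN3 (higher) and RET, TP63, GH1, R3HDML and FHAD1 (lower). Of the 24 genes, 12 had a low signal, 2 a middle and 0 a high one. Over all 24 genes, 22 of 36 other probe sets had the sign of the named one.

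Markers of choroid plexus and ependyma had the highest list median in SII, 0.38, with 7 of 9 members higher (RSPH1 0.41 ± 0.21, SLC4A5 1.08 ± 0.61). Heat shock and acute stress genes had a median of -0.07 with 18 of 29 lower (FKBP5 -1.86 ± 0.80, HSP90AB1 -0.49 ± 0.25). Hypoxia and glycolysis genes had a median of -0.07 with 14 of 21 lower (SLC2A1 -0.66 ± 0.45, PFKFB3 -0.63 ± 0.57). Markers of meninges and fibroblasts had a median of -0.12 with 10 of 14 lower (LUM, a collagen-binding proteoglycan, -1.55 ± 0.50, IGFBP2 -0.47 ± 0.26). The adjusted p in cameraPR were 0.381, 0.381, 0.415 and 0.415. The meninges list depended on the arrays used. Its median was -0.42 (adjusted p 0.00138) without SII control 1, which was that of a female animal with raised hybridisation controls, -0.44 with males only (0.00983) and -0.44 without the 3 arrays with raised controls (0.00914). With the correlation between its genes estimated (0.275, 0.339 and 0.437) none of these passed (0.472, 0.544 and 0.501). It was 0.19 (0.899) without SII control 2, so that the direction changed. It was -0.33 (0.308) without SII trained 1, -0.07 (0.448) without SII trained 2 and -0.03 (0.652) without SII trained 3.

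In limma, 0 of 52766 probe sets passed 5% in SII (smallest adjusted p 0.116), and 2043 (3.87%, with 1333 higher and 710 lower) had an unadjusted p under 0.05, where 2638 would be expected by chance. With 1 array left out at a time this count ran from 1921 to 3132. A plain 2-sample test also gave 0. The trained and control values did not overlap in 3737 probe sets (7.08%), where chance gives 10%. Of 29 lists, 0 passed in cameraPR or with an estimated correlation, 3 had an unadjusted p under 0.05, and fry gave 0 in 1 direction and 1 in either direction (T cells and granulocytes, adjusted p 0.000609). NKG7 was the only member of that list with an unadjusted p under 0.05 in limma. Without SII trained 3, 5 probe sets passed.

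Around the intraparietal sulcus, GDNF was lower in trained animals, with a change of -1.66 ± 0.25 (SE, n = 3 per group) and group means of 0.94 ± 0.45 in controls and -0.71 ± 0.23 in trained animals (SD). All 3 trained arrays of its single probe set lay at the floor and no control array did, so the size of this change depends on where the floor lay in those arrays. The 3 trained values differ only as the floors of their arrays do (offsets of -0.71, -0.80 and -0.36). Their SD is therefore no spread of animals, and the SE and the p of GDNF in IPS have no firm reading. With 1 common floor for all arrays, which in IPS raised only the trained arrays, the change was -0.74 ± 0.20. RET had a change of 0.80 ± 0.37, from 1.67 ± 0.57 in the probe set with no floor found and -0.08 ± 0.38 in the one where all 3 trained arrays lay at the floor. BDNF had a change of -0.29 ± 0.41, NTF3 of 0.11 ± 0.40, NTF4 of -0.22 ± 0.39, NTRK3 of -0.16 ± 0.20, NGFR of 0.46 ± 0.40, GFRA1 of 0.13 ± 0.34 and GFRA2 of 0.11 ± 0.43. GDNF passed 5% adjusted over the list alone (0.000398, range over alternatives 0.000239 to 0.0414) and not over all genes (0.312), and at least 1 gene past 5% over a list alone came up in 50.66% of 10000 shuffles of gene names.

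The rule named 12 higher and 12 lower genes in IPS, and none passed over all probe sets (adjusted p from 0.402 to 0.842). CLCN3, an endosomal chloride and proton exchanger and the only one with a high signal, had a change of 0.93 ± 0.21 with the same sign in 3 of 3 other probe sets. PPTC7, a mitochondrial phosphatase, had 1.66 ± 0.29 (2 of 2), DSCC1 2.17 ± 0.39, PRSS2 2.34 ± 0.39 (1 of 2), UBASH3B 2.90 ± 0.63 (2 of 3) and TTC39B 2.10 ± 0.48 (0 of 1). Among the lower ones were TCF3, a helix-loop-helix transcription factor, at -2.26 ± 0.33 (4 of 6), IKBKE, a kinase of interferon signalling, at -1.94 ± 0.30 (0 of 1), FGD6 at -1.45 ± 0.28, SMR3A at -1.78 ± 0.36, TAF6L at -2.51 ± 0.54 and CORO1B at -1.35 ± 0.30. The other 12 had floor values, namely TNFSF10, HABP2, LHX8, SLCO4C1, CHST9 and ASB4 (higher) and HOXA9, GDNF, NLRX1, ITGB3, IPPK and CLSPN (lower). Among the 24 genes, 1 had a high signal, 4 a middle and 7 a low one. Of 39 other probe sets of the 24 genes, 28 had the sign of the named one.

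Markers of excitatory neurons had a median change of 0.21 in IPS with 13 of 16 higher (FEZF2 0.71 ± 0.32, NEUROD6 0.59 ± 0.37). Immediate early genes, which respond to neuronal activity, had a median of -0.13 with 17 of 25 lower (FOSL2 -0.32 ± 0.23, KLF4 -0.79 ± 0.60). Axon growth and cytoskeletal plasticity genes had a median of 0.08 with 30 of 42 higher (SLIT1 1.20 ± 0.46, EFNB2 0.77 ± 0.35). None of these lists passed (adjusted p 0.363 for all 3 in cameraPR). Red blood cell genes had the highest median, 0.41, with 5 of 7 higher and an adjusted p of 0.757.

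In limma, 0 of 52766 probe sets passed 5% in IPS (smallest adjusted p 0.402), and 1726 (3.27%, with 956 higher and 770 lower) had an unadjusted p under 0.05. With 1 array left out at a time this count ran from 1592 to 2829. A plain 2-sample test also gave 0. The groups did not overlap in 5007 probe sets (9.49%), where chance gives 10%. Of 29 lists, 0 passed in cameraPR or with an estimated correlation, 3 had an unadjusted p under 0.05, and fry gave 0 in 1 direction and 1 in either direction (neurotrophins and their receptors, adjusted p 0.00269). In that list GDNF, with its trained arrays at the floor, had p 4.42e-05 in limma. The other members had p from 0.0552 (RET) to 0.796 (GFRA2). Without IPS trained 1, 2 probe sets passed, of which 1 had a name (CLDN18, -2.96 ± 0.25, adjusted p 0.0343, chosen after its values were seen).

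**Figure D2:**
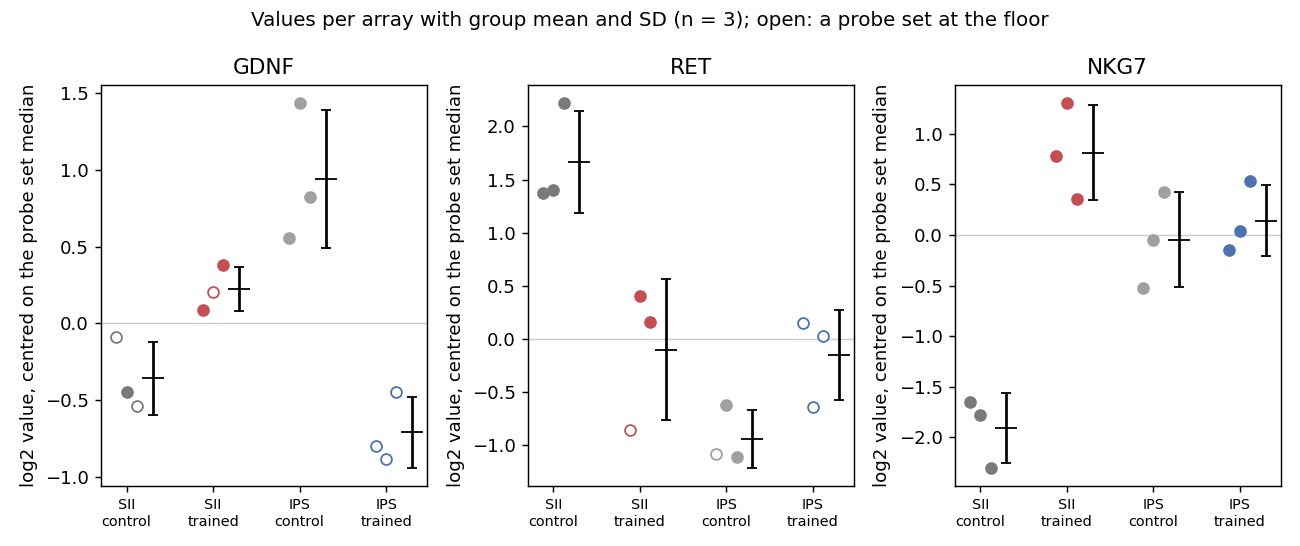
Centred log2 values of GDNF, RET and NKG7 in each array of the 4 groups (points), with the group mean and SD beside them (n = 3). Open points mark arrays where a probe set lay at the floor: for GDNF these were 2 SII control, 1 SII trained and all 3 IPS trained arrays, and for NKG7 there were none.

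The other lists had small medians in both regions, and none passed. Synaptic genes had medians in SII and IPS of 0.00 and 0.10 for presynaptic vesicle release, -0.02 and 0.06 for glutamate receptors and the postsynaptic density, -0.08 and 0.08 for GABA synthesis and receptors, -0.02 and 0.13 for monoamine and acetylcholine receptors and -0.07 and 0.09 for potassium and sodium channels. GABA neuron markers had medians of 0.02 and -0.01, and neuropeptides and granins of 0.05 and 0.01. Glial markers had medians of -0.11 and 0.00 for astrocytes, 0.08 and 0.20 for oligodendrocytes, 0.12 and 0.17 for their precursors and -0.01 and 0.18 for microglia and macrophages. Microglial genes in IPS included CD74 at 1.18 ± 0.39 and PTPRC at 0.66 ± 0.30. Endothelial cells and pericytes had medians of -0.02 and 0.03, T cells and granulocytes of -0.12 and 0.19, and interferon and inflammation genes of -0.06 and -0.07. Perineuronal net and extracellular matrix genes had medians of 0.05 and 0.08, and among them the protease gene MMP9 had a change of 1.39 ± 0.43 in IPS. Cadherins had medians of -0.01 and 0.03, mitochondrial respiratory chain genes of -0.01 and 0.08, and ribosomal proteins of 0.01 and 0.03. Markers of neighbouring tissue had medians of 0.04 and -0.01 for striatum and claustrum and 0.03 and 0.08 for hippocampus and amygdala. The median, the mean and the direction of the test differed in sign in SII for presynaptic vesicle release, striatum and claustrum, GABA neurons, oligodendrocytes, T cells and granulocytes, neurotrophins and cadherins. In IPS they differed for neurotrophins, endothelial cells, neuropeptides, ribosomal proteins, heat shock, GABA synthesis, cadherins and choroid plexus. Under another scaling the median changed sign in SII for presynaptic vesicle release, neuropeptides, perineuronal net, ribosomal proteins, GABA neurons, oligodendrocytes, their precursors, striatum and claustrum, and hippocampus and amygdala, and in IPS for neuropeptides and endothelial cells.

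**Figure D3:**
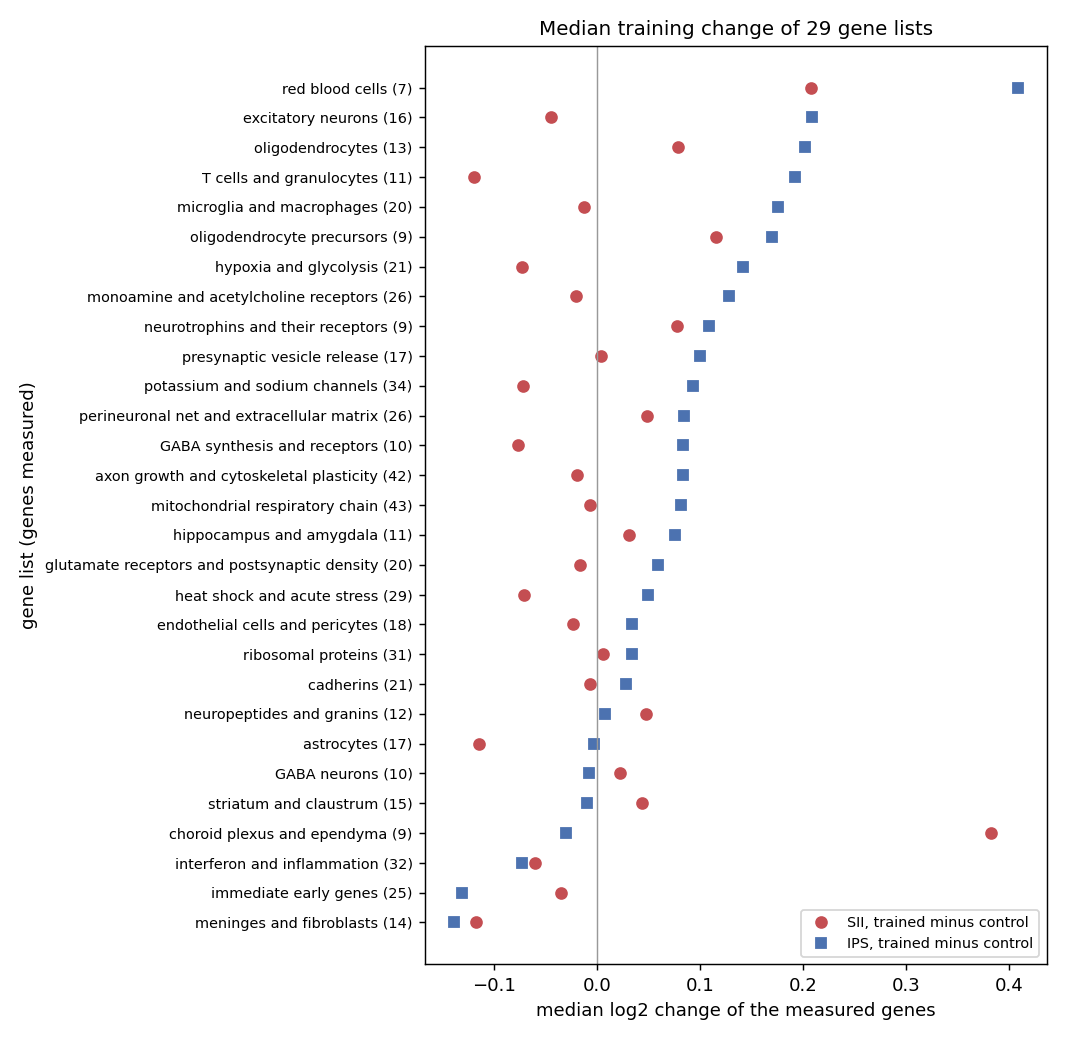
Median log2 change (trained minus control) of the measured genes of each of 29 lists, in SII (circles) and IPS (squares), with the number of genes measured in brackets. The medians lie between -0.12 and 0.38 in SII and between -0.14 and 0.41 in IPS, and no list passed 5%.

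The difference of the training changes between the regions asked whether a gene responded differently in IPS than in SII. RET differed by 2.57 ± 0.52 (SE; change of -1.77 in SII and 0.80 in IPS, n = 3 per group), and its probe set with no floor found by 3.00 ± 0.79. NKG7, with no floor found, differed by -2.52 ± 0.46, its change being 2.71 in SII and 0.19 in IPS. GDNF differed by -2.24 ± 0.35 on the deposited scale and by -0.80 ± 0.28 with 1 common floor. Because GDNF lay at the floor in 3 of 6 SII arrays and in all IPS trained arrays, its change in SII, and with it the difference, cannot be read from this probe set. These 3 genes passed 5% adjusted over the list alone (RET 0.00215, NKG7 0.0024, GDNF 0.000511) and not over all genes (0.781, 0.618 and 0.464). RET and NKG7 kept that call in 23 of 23 alternatives each (adjusted p over the list alone from 0.00103 to 0.0208 and from 0.00117 to 0.00908), and GDNF lost it with the common floor (0.0819).

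Of the 12 genes named for the difference, 8 had no floor found: F2, which encodes prothrombin, at 2.76 ± 0.53, CUL9 at 3.62 ± 0.75, PRSS2 at 2.54 ± 0.55, UBASH3B at 4.07 ± 0.88, PPP1R10 at 3.19 ± 0.71, CORO1B at -2.25 ± 0.42, NKG7 and TET3, a DNA demethylase, at -3.06 ± 0.59. TP63, GDNF, CD58 and FABP4 had floor values, and of the 8 with no floor found 6 had a low and 2 a middle signal. None passed over all probe sets (adjusted p from 0.396 to 0.832), and 8 of 20 other probe sets had the sign of the named one. Hypoxia and glycolysis genes differed with a median of 0.17 and 17 of 21 higher in IPS (PKM 1.28 ± 0.77, PFKFB3 1.26 ± 0.79), and axon growth genes with a median of 0.14 and 31 of 42 higher (DCX, a microtubule protein of young neurons, -0.87 ± 0.37, EPHB1 0.86 ± 0.51). Their adjusted p in cameraPR were 0.332 and 0.378. T cell and granulocyte genes had the highest median, 0.47, and choroid plexus markers the lowest, -0.27.

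In limma, 0 of 52766 probe sets passed for the difference (smallest adjusted p 0.302), and 1944 (3.68%; 862 higher, 1082 lower) had an unadjusted p under 0.05. In 163 probe sets the groups did not overlap in both regions and the changes had opposite signs, where chance gives 10% without overlap in each region. Of 29 lists, 0 passed in cameraPR or with an estimated correlation, 2 had an unadjusted p under 0.05, and fry gave 0 in 1 direction and 1 in either direction (neurotrophins and their receptors, adjusted p 8.36e-06). In limma the small p in that list were those of GDNF (5.68e-05), whose difference cannot be read, and RET (0.000477). Its other members had p from 0.197 to 0.876, and fry was not run without GDNF. Median, mean and test differed in sign for interferon and inflammation, perineuronal net, cadherins, oligodendrocyte precursors and endothelial cells. Without IPS trained 1, 2 probe sets passed, of which CLDN18 (-3.72 ± 0.33) had a name and was chosen after its values were seen.

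Averaged over both regions, NKG7 was higher in trained animals by 1.45 ± 0.24 and FOXP2 by 0.60 ± 0.15 (SE, 6 trained and 6 control arrays), and both passed 5% adjusted over the list alone (0.00097 and 0.022) and not over all genes. As many as 2 came up in 25.78% of 10000 shuffles of gene names. The change of NKG7 in IPS alone was 0.19. FOXP2 lost its call in 11 of 25 alternatives (adjusted p over the list alone from 0.0199 to 0.640), and its average change ran from 0.51 to 1.18. PPTC7 had an average change of 1.43 ± 0.21, ATP9B of 2.19 ± 0.38, TCF3 of -1.45 ± 0.24, C20H16orf78 of -1.72 ± 0.37, HYAL1 of -1.24 ± 0.29, XG of -1.30 ± 0.32 and SERPINA4 of -0.82 ± 0.20, each with non-overlapping groups in both regions and none past 5% (adjusted p from 0.467 to 0.909 over the 12 named genes). KLK3, ACOD1, HKDC1, PLG and E2F7, also named, had floor values, and of the others 6 had a low and 1 a middle signal. Markers of meninges and fibroblasts had a median of -0.16 with 9 of 14 lower (LUM -1.03 ± 0.36, ASPN -0.74 ± 0.27) and immediate early genes a median of -0.04 with 15 of 25 lower (KLF4 -0.85 ± 0.43, NR4A1 -0.56 ± 0.37), with an adjusted p of 0.344 for both. The meninges list passed without SII control 1 (median -0.30, adjusted p 0.00108), without IPS trained 2 (-0.18, 0.0422), with males only (-0.28, 0.00380) and without the 3 arrays (-0.35, 0.0147), but in none of these with an estimated correlation (0.390, 0.620, 0.466 and 0.737), and its median was 0.04 (0.812) without SII control 2, -0.07 (0.667) without IPS control 1 and -0.03 (0.785) without IPS trained 1. The immediate early list passed without SII trained 2 (-0.16, 0.0476; 0.581 with an estimated correlation) and had a median of 0.11 among high signals (0.940).

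In limma, 0 of 52766 probe sets passed for the average (smallest adjusted p 0.119), and 1836 (3.48%; 1178 higher, 658 lower) had an unadjusted p under 0.05. In 225 probe sets (0.426%) the groups did not overlap in both regions and the changes had the same sign, where chance gives 10% without overlap in each region, of either sign. Across probe sets, which are not independent, the changes in SII and IPS had a Pearson r of 0.00191 over all 52766 and 0.0507 over the 4479 with a high signal. Of 29 lists, 0 passed in cameraPR, with an estimated correlation or in fry, and 2 had an unadjusted p under 0.05. Median, mean and test differed in sign for neurotrophins, monoamine receptors, striatum and claustrum, T cells, presynaptic vesicle release, hypoxia, glutamate receptors, potassium and sodium channels, cadherins and neuropeptides. Without IPS control 2, 3 probe sets without a gene symbol passed.

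Between the regions, averaged over training, microglial markers had a median of -0.27 with 16 of 20 members lower in IPS than in SII, among them C1QB, a chain of complement C1q, at -0.70 ± 0.12 and CSF1R at -0.59 ± 0.18 (SE, 6 arrays per region). Axon growth and cytoskeletal plasticity genes had a median of -0.17 with 32 of 42 lower, with EPHA3, an ephrin receptor, at 1.02 ± 0.22, ROBO2 at -0.96 ± 0.24, RTN4 at -0.72 ± 0.19 and EFNB1 at 0.50 ± 0.14. Glutamate receptor and postsynaptic density genes had a median of -0.15 with 13 of 20 lower (CAMK2B -0.52 ± 0.16, GRIA1 -0.44 ± 0.14), ribosomal proteins a median of 0.08 with 23 of 31 higher (RPL23 0.44 ± 0.17, RPS7 0.44 ± 0.18), and the respiratory chain a median of 0.04 with 23 of 43 higher (COX8A -0.67 ± 0.19, SDHA 0.40 ± 0.12). Markers of choroid plexus and ependyma had the lowest median of the 29 lists, -0.29, with 8 of 9 lower (adjusted p 0.303). The adjusted p in cameraPR were 0.0754 for microglia and for axon growth, 0.283 for glutamate receptors, 0.168 for ribosomal proteins and 0.230 for the respiratory chain. With an estimated correlation the adjusted p were 0.272 for microglia and 0.865 for axon growth.

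Single genes adjusted over the list alone passed in 9 of 29 lists between the regions, 12 genes in all. In 10000 shuffles of gene names, which gave 4.92 on average, as many genes came up in 1.67% and as many lists in 1.31%. Lower in IPS were C1QB (0.00189), RET (-1.32 ± 0.26, 0.00346; group means of 1.66 in SII and -0.94 in IPS in controls, against -0.10 and -0.15 in trained animals, so that the difference lay in the controls), the VEGF receptor FLT1 (-1.12 ± 0.23, 0.0116), the sodium channel subunit SCN3B (-0.75 ± 0.15, 0.0141), the granzyme GZMA (-1.02 ± 0.27, 0.0388), GABRA3 (-0.76 ± 0.21, 0.0401), GPI (-0.51 ± 0.13, 0.0434), ROBO2 and RTN4 (0.0461 each). Higher in IPS were the neurofilament gene NEFH (0.91 ± 0.18, 0.00553), EPHA3 (0.0325) and EFNB1 (0.0462). Among 14132 genes, 2 passed over all genes, both with an adjusted p of 0.0417 and chosen after their values were seen. They were KIR2DL4, a receptor of natural killer cells, at -2.64 ± 0.32 with a low signal, and ACOD1, the enzyme that makes itaconate, at -1.47 ± 0.18. The group means of ACOD1 were 0.15 in SII control, 2.02 in SII trained, -0.53 in IPS control and -0.24 in IPS trained. Most of its difference thus lay in the trained animals. ACOD1 lay at the floor in 7 arrays, among them all 3 IPS controls, so its size has no firm reading, and RTN4 moved to -0.14 with 1 common floor. FLT1 and EPHA3 each had 1 of 2 probe sets at the floor, in 3 arrays for FLT1 and 2 for EPHA3. Over the alternatives C1QB kept its call in 25 of 25, NEFH in 27 of 28, RET in 22 of 24, FLT1 in 21 of 24 and SCN3B in 23 of 28, and the other 7 in fewer than 12 each. Sizes moved as well, from 0.38 to 1.15 for EPHA3 and -0.58 to -0.28 for GPI. GABRA3 ran from -0.89 to -0.46 and GZMA from -1.26 to -0.64.

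In limma, 0 of 52766 probe sets passed between the regions (smallest adjusted p 0.0790), and 4888 (9.26%; 2154 higher, 2734 lower) had an unadjusted p under 0.05. Of 29 lists, 0 passed in cameraPR or with an estimated correlation, 5 had an unadjusted p under 0.05, and fry gave 0 in 1 direction and 8 in either direction. Median, mean and test differed in sign for cadherins, neurotrophins, neuropeptides, oligodendrocytes and their precursors. Because region may coincide with hybridisation batch, neither can be told apart from the other here.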

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

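The tests against RNA quality, hybridisation controls and the floor were chosen only after the results were seen, while the shuffles of gene names and the splits of the samples were chosen before theirs were. RET (2.57), NKG7 (-2.52) and GDNF (-2.24) were singled out because their training changes differed between IPS and SII (log2, interaction in limma), past 5% when adjusted over the list alone and not over all genes.

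For RET, RNA quality as read by the actin 3' minus 5' difference was excluded as the whole cause. With that term in limma its difference was 2.40 (adjusted p over the list alone 0.00476). Its probe set with no floor found gave 2.70 ± 0.77 (p 0.00670) against 3.00 ± 0.79. The same holds for the 3 arrays with raised hybridisation controls, without which the values were 2.87 (0.00976) and 3.14 ± 1.09 (p 0.0244). With 1 common floor the difference was 2.32 ± 0.44 (0.0031, over all alternatives 0.00103 to 0.0208). That fit cannot decide on the floor, because it leaves the probe set with no floor found unchanged. In the other probe set all 3 IPS trained arrays lay at the floor. The unchanged probe set differed by 3.00 ± 0.79 (p 0.00348 in limma), so the floor found was not the whole cause there. For GDNF all 3 stay open, because the IPS trained arrays lay wholly at the floor and its difference cannot be read: -2.18 with the actin term, -2.51 without the 3 arrays and -0.80 ± 0.28 (0.0819) with 1 common floor decide nothing. The GAPDH 3' minus 5' control difference was not used as a term. It lay at -0.51 to -0.27 in the SII controls and -0.23 to 0.77 in the SII trained arrays, and the IPS groups overlapped. RNA quality as read by GAPDH was therefore not excluded for RET. Chance was not excluded either. Lists with 2 or more members past 5% came up in 3.87% of 10000 shuffles of gene names for this comparison, but as many members past 5% (3) in 7.86% and as many lists with one (2) in 23.06%, and the 3.87% belongs to 1 of 5 comparisons and to a criterion set after GDNF and RET had been noticed. A response of RET to training that differs between the regions stays open and untested.

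NKG7 rests on 1 probe set of low signal, with values from -2.30 to -1.65 in the SII controls and from 0.36 to 1.30 in the SII trained animals. Its difference kept its call in 23 of 23 alternatives (adjusted p over the list alone from 0.00117 to 0.00908). In limma its probe set gave -2.30 ± 0.44 with the actin term (p 0.000482) and -2.61 ± 0.49 without the 3 arrays (p 0.00126). Neither RNA quality as read by actin nor these arrays were therefore the whole cause. RNA quality as read by GAPDH stays open. No floor was found in the NKG7 probe set, and chance was not excluded.

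Other splits of the samples gave counts of unadjusted p under 0.05 as high as the real ones in every training comparison. In SII, 9 of 10 splits gave at least the real 2043 probe sets (highest other 6488) and 9 of 10 at least the real 3 lists (highest other 6). In IPS, 9 of 10 gave at least 1726 probe sets (highest other 2854) and 8 of 10 at least 3 lists (highest other 6). Each count of splits given here includes the real one, and with 10 splits no share can fall under 0.05. The SII split with 6488 probe sets, several times the real count, set SII control 1, SII trained 1 and SII trained 2 against the rest. That group held both female animals. It also held the higher actin 3' minus 5' differences (0.25, 1.17 and 0.63, against -1.87, -1.71 and -1.54 in the rest). This points to a structure of the samples, whose cause was not tested. For the difference, 76 of 100 drawn splits gave at least 1944 probe sets (highest other 6978) and 80 gave at least 2 lists (highest other 9). For the average, 87 of 100 gave at least 1836 probe sets (highest other 6447) and 76 gave at least 2 lists (highest other 9). The splits for the difference and the average regrouped the arrays of each region separately. An animal that gave both regions could thus count as trained in 1 and control in the other, so its pairing was not kept. Between the regions, 4 of 32 splits that exchanged the regions within an animal, or between animals of 1 training group that gave a single region, gave at least 4888 probe sets (highest other 5262) and 13 gave at least 5 lists (highest other 8). From these splits chance cannot be excluded for the difference, the average or the regions. Shuffles of gene names, which leave the grouping of the samples as it is, gave as many as the 12 genes past 5% over a list alone between the regions in 1.67%.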

How the results depend on the processing

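The fits with signal levels, the actin term, without the 3 arrays and with the floor removed or made equal were chosen after seeing the data. So were the list tests with the correlation estimated in each alternative fit, and the other fits of this section were not. Among probe sets (0 in each comparison), calls appeared in SII with quantile normalization (1), array weights (2), the sex term (2), high or middle signals (1) and a common floor (2). They appeared in IPS with high signals and array weights (1, CLCN3 0.95, adjusted p 0.0137, range 0.0137 to 1.00), in the difference with the actin term (1), and in the average with high or middle signals (1) and high signals with array weights (1, CLCN3). Between the regions 5 passed with quantile normalization (1 higher, 4 lower), 2 with the sex term, 1 with high signals, 1 with a common floor, 653 with high signals and array weights (569 higher) and 372 with high signals and the actin term (311 higher). The cause was not tested. Median centring, age, no animal correlation, males only, the region's 6 arrays alone, the 4 animals with both regions, leaving out the 3 arrays, the plain test and no floor probe sets gave 0. The replicate block gave 0 calls and 0 lists, and the replicate numbers pair nothing (r of arrays with the same number -0.20 to 0.06, as deviations from their group means).

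Lists passed (0 in each comparison) in SII with males only (1), high signals (2), without the 3 arrays (1), and high signals with array weights (2) or the actin term (1). In the difference they passed with array weights (1), high signals (2), high or middle signals (1), without the 3 arrays (1), and high signals with array weights (1) or the actin term (1). In the average they passed with males only (1), without the 3 arrays (1), and with high signals and the actin term (1). Between the regions they passed with array weights (3), sex (3), age (1), high signals (2), high or middle signals (2), without the 3 arrays (3), high signals with array weights (2) and the 4 animals (2). Without floor probe sets, with a common floor, and with high signals and an estimated correlation, 0 lists passed. With the correlation estimated in each alternative fit, also chosen after seeing the data, lists passed only between the regions: 1 (microglia) with high or middle signals or without IPS trained 2, and 3 in the 4 animals.

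Leaving out 1 array at a time gave 0 to 5 probe sets in SII (5 without SII trained 3), 0 to 2 in IPS and 0 to 2 in the difference (2 without IPS trained 1), 0 to 3 in the average (3 without IPS control 2), and 0 to 3 between the regions (3 without SII trained 3 or IPS trained 2, 1 without SII trained 2 or IPS trained 3). The lists that passed numbered 0 to 1 in SII, 0 to 0 in IPS and in the difference, 0 to 1 in the average, and 0 to 4 between the regions (4 without SII trained 2, 1 without SII control 1 or SII control 2). The named genes, none of which passed over all probe sets, also did not pass in 1769 of 1770 alternatives, with CLCN3 the exception. None changed sign, but in SII, IPS and the average they had been picked for non-overlapping groups, which largely fixes the sign. Calls over the list alone held in 358 of 521 alternatives and none changed sign. Probe sets with an unadjusted p under 0.05 numbered 1682 to 3030 in the difference with 1 array left out at a time. They numbered 1665 to 2619 in the average and 3804 to 5796 between the regions. A pseudocount and a filter keeping the probe sets with the highest mean could not be run on centred values, and no filter is how the data were analysed. In the simulations, which set no floor, changes of 2 were recovered in 83.7% of high probe sets and in 6.44% of those with the spread of floor probe sets. Whether the signal limited the calls in the data was not tested.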

Other observations

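The tests on the arrays of female animals and on the microglial markers were chosen only after the results were seen, as were the fits restricted by signal. Among probe sets with a high signal, hypoxia and glycolysis genes had a median of -0.12 over 11 members in SII (adjusted p 0.0119) and differed between the regions' training changes by 0.20 (0.0186), as did respiratory chain genes by 0.10 over 38 members (0.0186). Astrocyte markers had a median of -0.08 over 10 members in SII (0.0258). These calls rest on the preset correlation between genes of 0.01. With the correlation estimated among the high signals (0.318 for hypoxia, 0.289 for the respiratory chain, 0.152 for astrocytes) none passed (adjusted p 0.361 for both lists in SII and 0.556 for both differences). Over all signals the same lists had adjusted p of 0.415, 0.332, 0.779 and 0.596 at the preset correlation, where the hypoxia difference passed with array weights (0.25, 0.0436) and without the 3 arrays with raised hybridisation controls (0.36, 0.0227). With the actin term added among the high signals, the hypoxia list did not pass (-0.10, 0.0782, in SII and 0.18, 0.0778, for the difference), while the respiratory chain (0.13, 0.0127) and astrocyte markers (-0.12, 0.0285) did. With array weights added instead, the hypoxia list (-0.14, 0.00511, and 0.30, 0.0332) and astrocyte markers (-0.21, 0.00617) passed and the respiratory chain did not (0.15, 0.156). Over all signals the actin term moved the hypoxia median in SII from -0.07 to 0.00 (0.920).

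The arrays of the female animals stood apart on the first component, also without floor probe sets (117 and 127 against -59.3 to 4.42). Over the 10 arrays of males the component without floor probe sets rose with the hybridisation controls (Pearson r 0.660, permutation p 0.0350, adjusted 0.105 over 3 relations; Spearman rho 0.733, p 0.0203, adjusted 0.0610; r 0.812 without the 2 farthest arrays). That leaves less labelled RNA on these arrays as a candidate explanation, but neither test passed 5% once adjusted. IPS trained 3, from a male, was 1 of the 2 farthest arrays left out. Its controls lay at 0.46, as high as in SII control 1 (0.45), but its component was 4.42 against 117. Raised controls thus did not go with such a score in every array. The relations with the floor offset of the array (r 0.413, p 0.235; rho 0.515, p 0.133; r 0.731) and with the actin 3' minus 5' difference (r 0.154, p 0.668; rho 0.273, p 0.449; r 0.659) decide nothing over 10 arrays, so another scaling and RNA quality stay open. Sex, which these 2 arrays share, stays open, since IPS held no female animal.

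Microglial markers had a median of -0.27 in IPS against SII. Different animals in the regions were excluded as the whole cause, since within the 4 animals that gave both the median was -0.31 (adjusted p 0.00500; over the alternatives 0.00500 to 0.275, all at the preset correlation). With the correlation estimated in that fit the adjusted p was 0.00701, against 0.272 over all 12 arrays. In the 4 animals glutamate receptor genes (-0.30, adjusted p 0.0280 with the estimated correlation) and ribosomal proteins (0.16, 0.0280) differed as well. Markers of meninges and fibroblasts (-0.24) passed there at the preset correlation (0.0177) and not at the estimated one (0.321). With the actin term it was -0.19 (p 0.0569, adjusted 0.275), above the bound set for RNA quality but not beyond its spread, a condition added after the value was seen, so RNA quality stays open. The median of -0.27 cannot be told apart from regions hybridised apart, because the labels give no date. A difference between the regions themselves stays open and untested.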
